A study of Homo sapiens with 4 samples.

How the data were processed

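Total RNA was profiled from 4 libraries of human 1231A3 induced pluripotent stem cells (iPSCs) and of the aggregates made from them, with 1 library in each of 4 groups. Per the labels' protocols, single iPSCs were reaggregated in low-adhesion wells. The aggregates then received the TGF-beta receptor inhibitor SB431542 at 10 µM with BMP4, and later SB431542 with the GSK-3 inhibitor CHIR99021 at 1 µM. GSK-3 inhibition activates WNT signalling. The 4 groups were iPSCs at day 0, aggregates at day 5, cells with high CD271 sorted from day 5 aggregates, and day 5 aggregates that had received 10 nM all-trans retinoic acid (RA) from day 4. Per the same protocols, the RA was given in fresh medium with both inhibitors, whereas the untreated aggregates had no medium change between day 4 and day 5.

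Per the labels' protocols, 10 ng of total RNA was reverse transcribed and amplified in 13 cycles of multiplex PCR on an Ion AmpliSeq panel for the human transcriptome. This is a targeted panel with a short amplicon for each gene, so a count does not scale with transcript length, and a gene is seen only through its own amplicon. Amplicon efficiency differs between genes, so levels are compared between libraries for the same gene and not between genes. The authors deposited raw read counts per gene, with no normalization. The submitters' processing notes list the genome build hg19 and the tool DESeq2, with no role for either. The aligner and the counting program are not given in the sources used here. The annotation used here for symbols is of another build (GRCh38), so no coordinates are printed. Of the gene symbols in the count table, 19937 matched a current or older symbol in that annotation (18298 current and 1639 older), and 837 did not match. Genes are named as in the deposited counts. Reads of near-identical gene copies may not have been told apart by the authors' counting, which bears on gene families with close paralogs.

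The count table had 20812 rows. The 10 rows for ERCC spike-ins held 0 counts in all 4 libraries and were left out. A further 28 rows carried symbols turned into dates by a spreadsheet, 2 of these names occurring 2 times. They held between 0.216% and 0.296% of the counts of a library, stayed in the totals and in the counts of genes, and are not named. XIST and Y-linked genes were left out of every result. Total counts were 11274603 for iPSCs, 10935169 for day 5 aggregates, 11712609 for the CD271high-sorted cells and 11262025 for RA-treated aggregates. The 10 most abundant genes took between 6.89% and 8.52% of a library. A count of 0, which allows up to 3 counts, corresponds to at most 0.274 CPM (counts per 1000000 counts of the library) in the shallowest library and 0.256 in the deepest.

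With 1 library per group there is no replicate check of any difference, and no p-value was computed. Counts were scaled with edgeR 4.0.16 (TMM over all 4 libraries, R 4.3.3). The TMM factors were 1.065 for iPSCs, 0.99 for day 5 aggregates, 0.981 for sorted cells and 0.967 for RA-treated aggregates. A gene was measured in a comparison when its TMM-scaled CPM was at least 5 in the higher library, and was counted as higher or lower when the ratio was at least 2-fold. A count under 3 in the lower library was set to 3. No fold is printed against a count of 0: both counts are given. Ratios of named genes carry an exact 95% interval (Clopper-Pearson, for the ratio of 2 Poisson counts). PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and not the variation between cultures, RNA samples or amplifications.

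Before the data were examined, 4 comparisons, 26 gene lists, the rule for named genes and the alternative settings were fixed. The lists cover pluripotency, neural plate border, neural crest specifiers, mesenchymal, epithelial, HOX paralogue groups 1 to 5, HOX paralogue groups 6 to 13, forebrain and midbrain regional, hindbrain and posterior regional, retinoid response and metabolism, WNT targets, BMP targets, nodal and TGF-beta targets, surface ectoderm, preplacodal ectoderm, central nervous system progenitor, neuron, crest derivative, mesoderm and endoderm, amnion and trophoblast, proliferation, immediate early and dissociation stress, hypoxia and glycolysis, p53 targets, cholesterol synthesis and housekeeping genes. Some genes are members of several lists. For each list the median log2 ratio of the measured members was computed, with the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile describes these libraries and is not a test. An interval given for a list median is the 95% order-statistic interval over its members. The list members UTF1, CLDN6, HOXC4, SIX3, NKX1-2, MESP1 and ERVW-1 were not analysed here.

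The genes named in a comparison are 14 index genes, at most the 4 members of a described list with the largest absolute log2 ratio, and the 10 highest and 10 lowest ratios among genes at 20 CPM or more in the higher library. A gene named outside this rule is marked as chosen after its values were seen. Some genes that the rule selects are not reported here by name, and they remain in the sums, list medians and counts of genes. The procedure was tested on simulated data drawn from the real means and library sizes of each comparison, over 20802 genes. It recovered 100 of 100 genes at 3-fold and 100 of 100 at 8-fold in each of the 4 comparisons. The changed genes were drawn from those at 10 CPM or more in the 2 libraries pooled. This recovery therefore does not cover genes near the minimum of 5 CPM or ratios near 2-fold. Among unchanged genes it counted 2 of 10391 for day 5 aggregates against iPSCs, 0 of 9651 for sorted against unsorted cells, 1 of 9767 for RA-treated against untreated aggregates and 1 of 10317 for sorted cells against iPSCs. These simulations hold counting error alone.

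The alternatives were size factors of DESeq2 1.42.0, total counts, upper-quartile scaling, a minimum of 1 or 20 CPM, thinning of all libraries to the shallowest, a 1.5-fold or 4-fold rule, and, for list medians, log2 ratios of CPM + 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.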

Results

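The series asked which regional marker genes are expressed in neural crest cell aggregates that were made with or without retinoic acid (RA). The neural crest is an embryonic cell population that arises at the border of the neural plate and gives rise to peripheral neurons, glia, pigment cells and much of the facial skeleton. RA is a vitamin A derivative that acts through nuclear receptors and shifts developing tissue toward posterior identity. Gene counts from a targeted amplicon panel were compared between iPSCs at day 0, untreated aggregates at day 5, CD271high cells sorted from such aggregates, and aggregates that had received 10 nM RA from day 4. The line 1231A3 is a human iPSC line. CD271 is the nerve growth factor receptor, encoded by NGFR, and is used as a surface marker of neural crest cells. Each group had 1 library, of 11274603, 10935169, 11712609 and 11262025 counts in that order, with between 15351 and 16376 genes at 1 count or more. All values below compare single libraries, have no replicate check, and carry intervals for counting error only.

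The first comparison, of day 5 aggregates with iPSCs, addresses how cells at the end of induction differed from the starting cells. Pluripotency genes were lower and neural crest genes were higher at day 5. POU5F1, the core pluripotency transcription factor, was at 1456.5 CPM in iPSCs and 7.3 CPM at day 5, 199.5-fold lower (95% interval 160 to 252). NANOG was 36.8-fold lower (28.5 to 48.3). SOX10, a transcription factor of migrating crest cells, was at 4 CPM in iPSCs and 500.5 CPM at day 5, 125-fold higher (94.3 to 170.1). TFAP2A had 0 counts in iPSCs and 4154 counts (384 CPM) at day 5, and PAX3 was 764-fold higher (327 to 2354). FOXD3 was 7.38-fold higher (6.4 to 8.56) and NGFR was 23.6-fold higher (17.8 to 32), at 98.2 CPM.

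Of 11077 measured genes, 1532 (13.8%) were at least 2-fold higher at day 5 and 2009 (18.1%) at least 2-fold lower. The median log2 ratio over all measured genes was 0.05. Among pluripotency genes, 19 of 22 were lower, 0 were higher and 3 were within 2-fold, with a median log2 ratio of -4.46 (interval -7.48 to -1.91), at percentile 0 of the random lists. The largest differences in the list were at TDGF1, a co-receptor for nodal (4355 counts in iPSCs and 1 at day 5), ESRG (804-fold lower), PODXL (321-fold lower, 239 to 442) and PRDM14 (810 counts and 2). The neural crest specifier list had 17 of 23 members higher, 3 lower and 3 within 2-fold. Its median was 2.97 (1.72 to 6.32), at percentile 100. TFAP2B, NR2F1 and NR2F2 had 0 counts in iPSCs and reached 508, 410 and 80.1 CPM. CDH6, a cadherin of premigratory crest, was 834-fold higher (555 to 1315) at 1597 CPM. Of 11 measured neural plate border genes, 8 were higher and 3 lower, with a median of 5.35 (-2.40 to 9.58) at percentile 100. Besides TFAP2A and PAX3, MSX2 had 425 counts at day 5 against 0, and PAX7 had 229 against 1.

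**Figure D1:**
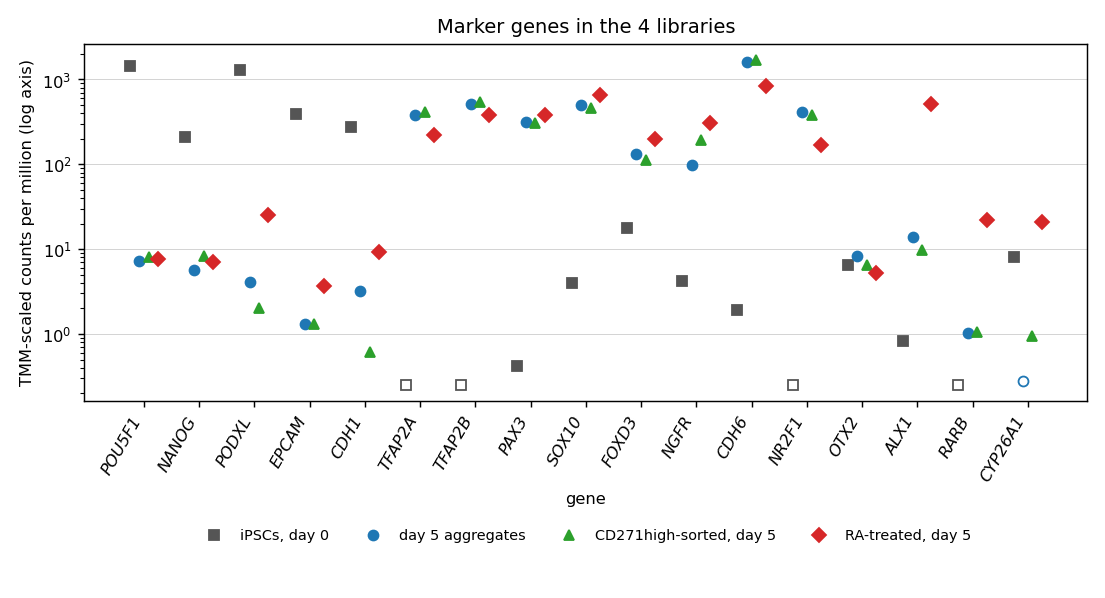
TMM-scaled CPM (log axis) of 17 marker genes in the 4 libraries, 1 point per library, with open symbols for counts under 3, drawn at the level of 3 counts. POU5F1 lay at 1456.5 CPM in iPSCs and between 7.3 and 8 CPM in the 3 day 5 libraries, and ALX1, RARB and CYP26A1 were highest in the RA-treated library.

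Epithelial genes were lower in 19 of 19 measured members (median -5.24, -6.41 to -4.61, percentile 0). EPCAM, an epithelial adhesion molecule, was 299-fold lower (178 to 548), CLDN7 was 133-fold lower, ESRP1, a splicing regulator of epithelial cells, was 114-fold lower, and CRB3 had 309 counts in iPSCs and 0 at day 5. In the mesenchymal list 9 of 14 members were higher and 4 lower (median 1.62, -1.48 to 4.29, percentile 100). ZEB2 and VIM were 439-fold (202 to 1198) and 19.6-fold (18.3 to 21.1) higher, ZEB1 had 133 counts against 2, and COL1A1 was 10.8-fold lower. The surface ectoderm list had 7 of 9 members lower and 2 higher (median -5.17, -6.41 to 3.71, percentile 0), led by EPCAM, CDH1 (85-fold lower) and GRHL2 (37.8-fold lower). Of 10 preplacodal ectoderm genes 8 were higher and 2 lower (median 4.52, -1.47 to 6.96, percentile 100), and EYA4 had 647 counts at day 5 against 0.

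Genes of the pathways targeted by the medium differed in several lists. Of 11 WNT target genes 7 were higher and 1 lower (median 2.5, -0.94 to 7.42, percentile 100). SP5 had 462 counts at day 5 and 0 in iPSCs, TNFRSF19 was 377-fold higher (147 to 1386), and NKD1, a feedback inhibitor of WNT signalling, was 30.4-fold higher (24.9 to 37.4). Of 13 BMP target genes 9 were higher and 2 lower (median 2.12, percentile 100). Among the higher ones were MSX2 and MSX1, with 425 and 110 counts against 0, which are also in the neural plate border list. The 2 lower ones, named after their values were seen, were ID1 (18.1 CPM against 40.9) and SMAD7 (4.62 against 21.8). Other lists hold 6 of the 16 BMP target genes. All 8 measured nodal and TGF-beta target genes were lower (median -2.70, percentile 0.02). FOXH1 had 801 counts in iPSCs and 0 at day 5, LEFTY1, also in the pluripotency list, had 71 and 1, and CTGF was 8.92-fold lower (7.07 to 11.4).

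Markers of other lineages were present as well. Of 12 neuron genes 9 were higher and 1 lower (median 3.67, percentile 100), and NEUROD4, NHLH1, NEUROG1 and STMN2 had 221, 178, 146 and 424 counts at day 5 against 0, 2, 0 and 12. The crest derivative list had 6 of 8 members higher and 1 lower (median 4.26, -1.82 to 7.15, percentile 100). Its member PDGFRA, a growth factor receptor gene, had 314 counts at day 5 against 2. Of 8 measured central nervous system progenitor genes 4 were higher and 3 lower (median 1.48, -3.96 to 4.99, percentile 99.96). DLL1 was 25-fold higher (12.9 to 55.5) and SOX3 15.6-fold lower (10.8 to 23.3), and with a minimum of 20 CPM the median of this list changed sign (-0.85). The amnion and trophoblast list had 4 of 7 members higher and 3 lower (median 3.52, -4.87 to 5.51, percentile 99.99), with TBX3 at 123 counts against 0 and KRT7 24.5-fold lower. The mesoderm and endoderm list had 2 measured members, KDR (27.3-fold lower) and TCF15 (22.8-fold lower).

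Among regional genes, 3 of 5 measured forebrain and midbrain genes were higher and 1 lower (median 4.75, percentile 100). LMX1B and DMBX1 had 313 and 185 counts at day 5 against 1 each, EMX2 had 73 against 0, and HESX1 was 10.4-fold lower (6 to 19.4). OTX2, a forebrain and midbrain transcription factor, was 1.28-fold higher at 8.32 CPM, and its log2 interval (-0.10 to 0.81) held 0. In the hindbrain and posterior list 4 of 10 members were higher and 1 lower (median 0.32, percentile 84.5), led by MEIS2, 67.7-fold higher (35.4 to 149). The 14 HOX genes of paralogue groups 1 to 5 together had 3 counts in iPSCs and 0 at day 5, and the 24 of groups 6 to 13 had 0 and 1. HOXB1, HOXA2 and HOXB2 had 0 counts in both libraries. The retinoid list had 3 of 10 members higher, 3 lower and 4 within 2-fold (median 0.26, percentile 76.8). Its member CRABP2 was 44-fold higher (41 to 47.4), LRAT was 209.9-fold lower (96.2 to 573), CYP26A1 had 1 count at day 5 against 97, and RARB had 11 against 1.

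Most proliferation genes lay within 2-fold (21 of 25, 2 higher and 2 lower, median -0.05, percentile 15.8). CCNE2 was 5.92-fold higher (4.56 to 7.79) and MCM5 2.24-fold lower (2.1 to 2.39). In the hypoxia and glycolysis list 11 of 17 members were lower and 0 higher (median -1.49, percentile 0). ADM had 919 counts in iPSCs and 0 at day 5, and the glucose transporter genes SLC2A3 and SLC2A1 were 12.5-fold and 8.43-fold lower. The p53 target list had 7 of 14 members lower and 3 higher (median -1.03, -3.28 to 1.04, percentile 0.31), with PMAIP1 154-fold lower (74.4 to 383). Cholesterol synthesis genes were lower in 4 and within 2-fold in 11 of 15 members (median -0.43, -1.09 to 0.14, percentile 1.64). In the immediate early and stress list 3 members were higher, 5 lower and 7 within 2-fold (median 0.10, percentile 61.8). EGR1 and FOS were 6.45-fold (5.31 to 7.91) and 4.18-fold (2.84 to 6.29) higher. Housekeeping genes, a yardstick only, had a median of -0.14 and an SD of 0.70 across 28 genes, and 3 of them were lower. The 10 highest ratios among genes at 20 CPM or more were at TFAP2B, NR2F1, TFAP2A, CDH6, NPR3, PAX3, KANK4, RELN, ZEB2 and TNFRSF19. The 10 lowest were at TDGF1, ESRG, NPTX1, CD9, STC2, PODXL, LCK, EPCAM, ADM and SMPDL3B.

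The second comparison, of CD271high-sorted cells with unsorted day 5 aggregates, addresses what the sort enriched. NGFR itself was at 192 CPM in the sorted and 98.2 CPM in the unsorted library, 1.96-fold higher (1.82 to 2.11), just short of the 2-fold rule. Other crest markers were close to their unsorted levels: SOX10 was 1.1-fold lower (1.06 to 1.14), FOXD3 1.17-fold lower (1.08 to 1.26) and PAX3 1.05-fold lower (0.996 to 1.09), and TFAP2A was 1.08-fold higher (1.04 to 1.13). Of 9998 measured genes, 23 were at least 2-fold higher, 60 at least 2-fold lower and 9915 within 2-fold. For 29 of these 83 genes the counting interval lay wholly beyond 2-fold. These counts depended on the expression minimum: at 20 CPM or more they were 8 higher and 6 lower.

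All 21 measured crest specifiers were within 2-fold, with a median of -0.13 (-0.34 to 0.01) at percentile 0.12. Apart from NGFR, the largest differences in the list were at TWIST1 (1.89-fold lower, 1.19 to 3.03), SOX9 (1.76-fold lower, 1.47 to 2.11) and SNAI1 (1.5-fold lower, 1.16 to 1.94). The neural plate border list had 1 of 11 members lower (median -0.26, -0.96 to 0.11, percentile 0.14). That was ZIC1, 4.62-fold lower (3.22 to 6.8). The crest derivative list had 8 of 8 members within 2-fold (median -0.36, -0.93 to -0.20, percentile 0.09), and DLX2 was 1.91-fold lower (1.61 to 2.27). The mesenchymal list had 12 of 12 within 2-fold (median -0.14, -0.24 to 0.09, percentile 0.36).

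Neuron genes were lower in 2 and within 2-fold in 10 of 12 members (median -0.43, -0.90 to -0.23, percentile 0). STMN2, a microtubule regulator of growing neurons, was at 39.2 CPM in the unsorted and 10 CPM in the sorted library, 3.92-fold lower (3.18 to 4.86), and INA, a neurofilament-associated protein gene, was 2.24-fold lower (1.69 to 2.99). BMP targets had 2 of 12 members lower (median -0.49, -0.98 to -0.14, percentile 0.01), GATA3 4.19-fold (2.43 to 7.61) and BMP4 3.26-fold (2.15 to 5.05). In the surface ectoderm list 2 of 5 members were lower (median -0.75, percentile 0.04), and KRT19 was 4.38-fold lower (2.51 to 8.11). In the amnion and trophoblast list 3 of 4 were lower (median -1.55, percentile 0), among them TBX3, 5.94-fold (3.75 to 9.82). The last 2 lists share 3 genes, GATA3 among them. KRT19, GATA3, BMP4 and TBX3 lay between 6.1 and 11.4 CPM in the unsorted library, near the minimum of 5 CPM.

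Each of the other lists had 1 member or none at 2-fold. The epithelial list had 1 of 5 members lower (median -0.21, percentile 10.6) and the preplacodal list 1 of 9 (FOXE3, 4.36-fold lower, median -0.15, percentile 6.96). The hindbrain and posterior list had 1 of 10 lower (EPHA4, 4.39-fold, median -0.18, -0.52 to 0.02, percentile 1.48). The central nervous system progenitor list had 1 of 7 lower (POU3F2, 3.38-fold, median -0.12, percentile 13.7). The pluripotency (10 genes), retinoid (7), WNT target (10), forebrain and midbrain (4), hypoxia (14), p53 target (11), proliferation (25) and nodal and TGF-beta target (2) lists had 0 members at 2-fold. OTX2 was 1.29-fold lower, with a log2 interval of -0.83 to 0.09. Cholesterol synthesis genes had a median of 0.19 (0.11 to 0.31, percentile 99.94), with 14 of 14 within 2-fold. In the immediate early and stress list 1 of 12 was higher (median 0.11, percentile 92.7): FOS, 2.16-fold (1.75 to 2.67), and EGR1 was 1.74-fold higher (1.58 to 1.91). Housekeeping genes had a median of 0.09 (percentile 98.4) and an SD of 0.16. CYP26A1 had 11 counts against 1, RARB 12 against 11, and all HOX genes of groups 1 to 5 had 0 counts in both libraries. The highest ratios at 20 CPM or more were at NAT14 (2.9-fold, 2.26 to 3.75), SLC7A11, a cystine transporter gene (2.28-fold, 2.1 to 2.47), FAM193A, FOS, AVEN, ZNF460, SCAF8, FBXO11, NGFR and MAK16. The lowest were at STMN2, HAPLN1 (2.91-fold lower, 2.49 to 3.41), DLL3, LPL, PCYT1B, DSP, NEFM, IFI16, DLX2 and COL5A2.

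The third comparison, of RA-treated with untreated day 5 aggregates, addresses the regional identity of the crest cells, which HOX genes mark. HOX genes of paralogue groups 1 to 5 had 108 counts in the RA-treated library and 0 in the untreated one. The summed level was 9.92 TMM-scaled CPM (exact Poisson interval 8.14 to 12) in the RA-treated library and 0 (0 to 0.341) in the untreated one. Reads were found for 12 of the 14 genes, 5 of them with 3 counts or more. HOXB1 had 49 counts against 0. HOXB5 had 10 counts, HOXA3 7, HOXB2 4 and HOXA2 2; HOXB5 and HOXA3 are named after their values were seen. Groups 6 to 13 had 5 counts in the RA-treated library and 1 in the untreated one. No single HOX gene reached 5 CPM, so none entered the counts of genes below, and levels of a few counts give little precision.

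**Figure D2:**
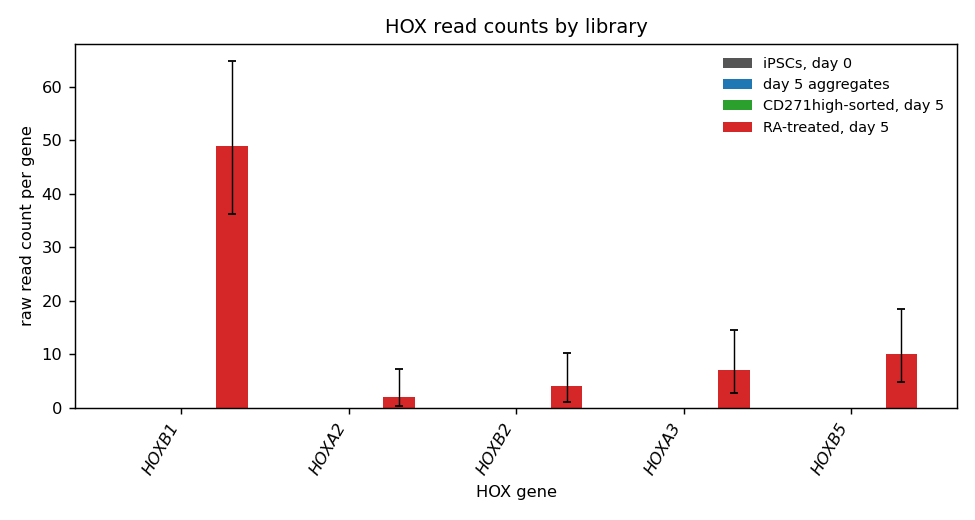
Raw read counts of HOXB1, HOXA2, HOXB2, HOXA3 and HOXB5, as bars from 0 for the 4 libraries, with exact 95% Poisson intervals of counting error. HOXB1 had 49 counts in the RA-treated library, and the untreated and sorted day 5 libraries had 0 counts for each of these genes.

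Several genes known to respond to RA were higher in the RA-treated library. CYP26A1, which encodes an RA-degrading enzyme, had 225 counts against 1 (interval of the ratio 39.7 to 8872). RARB, an RA receptor gene, was 21.5-fold higher (11.8 to 43.7), DHRS3, a retinaldehyde reductase gene, 7.86-fold (4.97 to 13), and RARA 5.85-fold (4.87 to 7.08). The retinoid list had 6 of 10 members higher, 0 lower and 4 within 2-fold, with a median of 2.32 (-0.42 to 4.43) at percentile 100. CRABP2, one of those within 2-fold and named after its values were seen, was at 1568.9 CPM against 2739.6. Over all genes, 528 of 10242 measured (5.16%) were at least 2-fold higher and 275 (2.69%) at least 2-fold lower. For 393 of these 803 genes the counting interval lay wholly beyond 2-fold. RA-treated aggregates had also received fresh medium at day 4 and the untreated ones had not, so the differences of this comparison belong to RA and the medium change together.

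Crest markers were expressed in the RA-treated library, at levels both above and below the untreated ones. SOX10 was 1.3-fold higher (1.25 to 1.34), PAX3 1.21-fold (1.15 to 1.26) and FOXD3 1.52-fold (1.42 to 1.62). TFAP2A was 1.72-fold lower (1.63 to 1.81). NGFR was at 307 CPM, 3.13-fold higher (2.92 to 3.36) than in the untreated library and 1.6-fold higher (1.51 to 1.69) than in the sorted one. The crest specifier list had 4 of 22 members higher, 1 lower and 17 within 2-fold (median 0.55, -0.42 to 0.70, percentile 100). MOXD1 was 26.2-fold higher (17.4 to 41.2), SOX9 5.88-fold (5.23 to 6.62) and SNAI1 5.4-fold (4.54 to 6.47). The crest derivative list had 3 of 9 higher and 0 lower (median 0.48, -0.03 to 5.05, percentile 98.5). ALX1, a homeobox gene of facial mesenchyme, was at 508 CPM against 13.8, 36.9-fold higher (31.3 to 43.7). DLX1 was 2.04-fold higher (1.49 to 2.82). In the neural plate border list 2 of 11 members were lower and 0 higher (median 0.00, percentile 51.6): TFAP2C, 3.87-fold (3.43 to 4.38), and ZIC5, 2.73-fold (1.94 to 3.92). In the mesenchymal list 2 of 13 were higher and 2 lower (median -0.16, percentile 14.2), with CDH11 and VIM 3.5-fold (2.83 to 4.37) and 2.18-fold (2.12 to 2.25) lower.

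Anterior regional genes were lower in part. Of 6 measured forebrain and midbrain genes 3 were lower and 1 higher (median -0.87, -2.08 to 2.03, percentile 0.26). DMBX1 was 4.23-fold lower (3.03 to 6.02), EMX2 2.62-fold (1.68 to 4.21) and LMX1B 2.11-fold (1.73 to 2.59), and OTX1 was 4.07-fold higher (2.48 to 7.02). OTX2 had 57 counts against 90, 1.59-fold lower (1.13 to 2.25). In the hindbrain and posterior list 4 of 12 members were higher and 1 lower (median 0.21, percentile 83.8). The HOX cofactor gene MEIS1 was 3.88-fold higher (2.6 to 5.96), CDX1 was 3.91-fold higher (2.23 to 7.26) and IRX3 2.6-fold (2.06 to 3.3). Preplacodal genes were lower in 3 and within 2-fold in 6 of 9 members (median -0.65, -3.95 to -0.19, percentile 0.185). FOXE3, a lens placode gene, was 23.1-fold lower (9.63 to 72.6) and DLX3 3.07-fold (2.35 to 4.05).

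**Figure D3:**
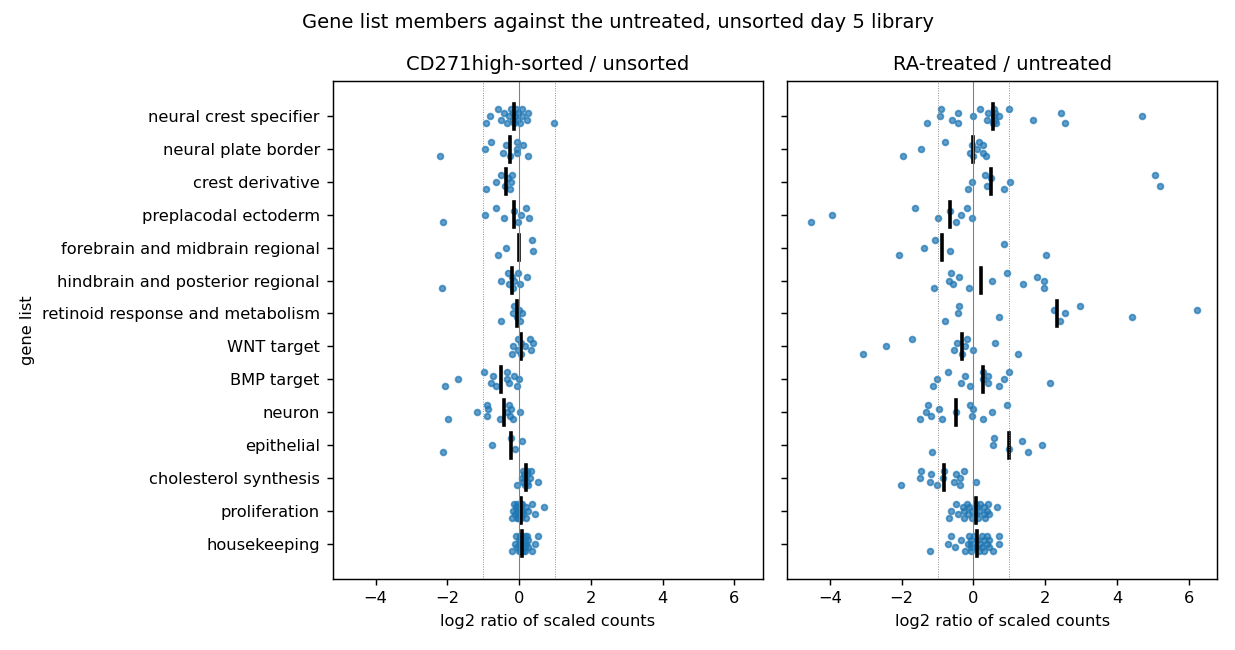
Log2 ratios of the measured members of 14 gene lists against the untreated, unsorted day 5 library, for sorted cells (left) and RA-treated aggregates (right), with a point per gene, black bars for list medians and dotted lines at 2-fold. The retinoid list median is 2.32 in the RA-treated library, and the cholesterol synthesis median is -0.83 there and 0.19 in the sorted one.

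WNT targets had 3 of 11 members lower and 1 higher (median -0.31, percentile 3.78): SP5 was 8.45-fold lower (6.38 to 11.4), RNF43 5.4-fold (2.81 to 11.4) and NKD1 3.25-fold (3.01 to 3.51), and NKD2 was 2.39-fold higher (1.54 to 3.78). BMP targets had 1 of 14 higher (BMPER, 4.37-fold, 3.12 to 6.23) and 2 lower (median 0.27, percentile 89.6). Of 4 nodal and TGF-beta targets 2 were higher (TGFBI and SKIL) and 1 lower (CTGF, 2.65-fold, median 0.75, percentile 93.4). Cholesterol synthesis genes were lower in 6 and within 2-fold in 8 of 14 members, with a median of -0.83 (-1.47 to -0.37) at percentile 0. STARD4 was 4.02-fold lower (2.89 to 5.71), HMGCS1, the HMG-CoA synthase gene, 2.79-fold (2.62 to 2.97), SQLE, the squalene epoxidase gene, 2.77-fold (2.4 to 3.2), and MSMO1 2.31-fold (2.13 to 2.51). In the immediate early and stress list 4 of 12 members were lower and 1 higher (median -0.39, -1.36 to 0.03, percentile 0.96). FOS was 9.2-fold (5.29 to 17.3), EGR1 5.62-fold (4.63 to 6.85) and ATF3 2.56-fold (1.94 to 3.42) lower, and the heat shock gene HSPA1A was 2.42-fold higher (2.14 to 2.72). The p53 target list had 2 of 11 lower, FAS and CDKN1A (median -0.43, -1.15 to 0.10, percentile 1.13), and the hypoxia list 1 of 13 higher, SLC2A1, 2.41-fold (2.27 to 2.56, median 0.01, percentile 54.7).

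Neuron genes were lower in 4 and within 2-fold in 9 of 13 members (median -0.48, -1.26 to 0.25, percentile 0.25). DCX was 2.8-fold lower (2.35 to 3.36), SYT1 2.52-fold, NEUROD1 2.4-fold and TUBB3 2.29-fold (2.09 to 2.5). Of 9 central nervous system progenitor genes 4 were higher and 1 lower (median 0.31, percentile 91.4), and PAX6, a neural progenitor transcription factor gene, was 3.04-fold higher (2.18 to 4.31). Epithelial genes had 3 of 7 higher and 1 lower (median 0.99, -1.16 to 1.91, percentile 99.9), with KRT19 3.75-fold (2.85 to 5), CDH1 2.87-fold (1.93 to 4.34) and KRT18 2.54-fold (2.01 to 3.22) higher. The surface ectoderm list shares these genes and had 3 of 6 higher and 1 lower (median 0.96, -1.95 to 1.91, percentile 99.8). In the amnion and trophoblast list 1 of 4 was higher, TBX3, 5.01-fold (4.12 to 6.13), and 2 were lower (median -0.96, percentile 0.3). Of 11 pluripotency genes 1 was higher, PODXL, 6.23-fold (4.52 to 8.78, median -0.06, percentile 45.4), and the log2 intervals of POU5F1 (-0.38 to 0.54) and NANOG (-0.18 to 0.84) held 0. All 25 proliferation genes were within 2-fold (median 0.06, percentile 81.9). Housekeeping genes had a median of 0.09 and an SD of 0.44, with EMC7 2.3-fold lower.

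Among the highest ratios at 20 CPM or more were STC2 (105-fold, 35.7 to 514), CYP26A1, FNDC5 (73.1-fold, 41.7 to 142), SPP1, the osteopontin gene (64.9-fold, 37 to 126), ALX1, MOXD1, RARB, FOXC1 (20.6-fold, 11.6 to 40.5) and MAP7. Among the lowest were RELN, which encodes reelin (20-fold lower, 15.5 to 26.3), ECEL1 (15.1-fold, 12.6 to 18.1), ABCC2, the receptor tyrosine kinase gene KIT (11.8-fold, 8.87 to 16.2), SP5, DACT1, a WNT pathway modulator gene (7.23-fold, 6.42 to 8.17), COL5A3, PRELP and UNC5C. RELN was among the highest ratios of day 5 aggregates over iPSCs and STC2 among the lowest, and both comparisons use the same untreated day 5 library.

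The fourth comparison, of sorted cells with iPSCs, gives the induction as seen in the sorted cells and shares its libraries with the comparisons above. Of 11079 measured genes 1556 were higher and 2050 lower. Pluripotency genes were lower in 20 of 22 members (median -4.57, percentile 0), and POU5F1 was 182-fold lower (148 to 226). Crest specifiers were higher in 15 and lower in 2 of 22 members (median 2.96, 0.42 to 6.83, percentile 100). SOX10 was 114-fold higher (85.9 to 155), NGFR 46.2-fold (34.9 to 62.5) and FOXD3 6.33-fold (5.47 to 7.34). Epithelial genes were lower in 19 of 19 members (median -6.19, percentile 0). CDH1 was 452-fold lower (219 to 1124).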

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

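All alternatives in this part were planned, and none was added later. Leaving out a library was not possible with 1 library per group. In each comparison the numbers of genes higher and lower stayed within 1.5 times the reported ones under DESeq2 size factors, total counts, upper-quartile scaling and thinning to the shallowest library (8 of 8 counts under each). Of the 64 counts computed, 28 moved further, all under another expression minimum or size rule, by construction: a looser rule lets more genes pass and a stricter one fewer.

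With a minimum of 1 CPM, 3017 genes were lower in day 5 aggregates than in iPSCs and 3090 in sorted cells than in iPSCs. In sorted against unsorted cells 173 were then higher and 382 lower, and in RA-treated against untreated aggregates 991 and 612. With a minimum of 20 CPM the numbers higher and lower were 1001 and 1074 (day 5 against iPSCs), 8 and 6 (sorted against unsorted), 281 and 128 (RA) and 1032 and 1083 (sorted against iPSCs). Under a 4-fold rule they were 478 and 1106, 1 and 11, 122 and 37, and 460 and 1144 in the same order. Under a 1.5-fold rule 2823 genes were higher at day 5 than in iPSCs and 2851 in sorted cells than in iPSCs. The same rule gave 185 higher and 225 lower for the sort, and 1374 and 1049 for RA.

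Of 624 list medians computed under alternatives, 619 stayed the same by the rule used, 1 moved and 4 were counted as changed in sign. A change of sign was counted only for lists outside the middle 95% of their random lists. Any other median counted as the same inside its interval over members, or within 1 SD of the members where no interval was given. Medians near 0 could therefore change sign and still count among the 619, such as proliferation in sorted cells against iPSCs (0.01). The epithelial median of day 5 against iPSCs was -4.53 with log2(CPM + 1), which shrinks ratios of low counts by construction. The central nervous system progenitor median of day 5 against iPSCs was -0.85 with a minimum of 20 CPM. In sorted cells against iPSCs the BMP target median was -0.22 with that minimum, and with 1 CPM the forebrain and midbrain median was -0.013 and the amnion and trophoblast median 2.48. A minimum of CPM sets which members enter a median, and the cause was not tested further. At 20 CPM, 78 of 91 medians could be computed. Of 1684 values of named genes, 1667 stayed within their counting interval, 17 moved, all under total counts, and 0 of those at 2-fold or more changed direction. Total counts put the median of all genes at -0.07 in place of 0.05 for day 5 against iPSCs, and at -0.07 in place of 0.06 for sorted cells against iPSCs. The summed HOX level of the RA-treated library stayed within its counting interval in 4 of 4 alternatives. Apart from thinning, these only rescale the same counts. At this depth the summed HOX level of the RA-treated library has a counting interval of 8.14 to 12 CPM, and no single HOX gene reached 5 CPM.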

Other observations

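All of the gene families and tests in this part were chosen after the results were seen. Gene families were taken by symbol, and each median below kept its sign under TMM, DESeq2, total-count and upper-quartile scaling. More families were computed, each in all 4 comparisons, than are described here. These scalings shift all genes of a comparison alike and by little (1.209 to 1.315 for protocadherins at day 5 against iPSCs). The kept sign is therefore a weak check. In day 5 aggregates against iPSCs, 12 of 19 measured protocadherin genes were higher and 2 lower, with a median log2 ratio of 1.31 (interval over members 0.50 to 2.66). PCDH10 was at 180 CPM against 2.5. Of 15 semaphorin genes, which encode guidance cues for axons and migrating cells, 8 were lower and 1 higher (median -1.13, with an interval over members of -2.49 to 0.36 that held 0). SEMA6A was at 61.3 CPM against 334, while SEMA3C was higher, at 56.6 CPM against 0.5. In RA-treated against untreated aggregates, 4 of 9 cadherin genes were lower and 1 higher (median -0.93, -1.16 to -0.16), and CDH11, one of the 4, was at 10.1 CPM against 35.4. Of 6 laminin genes, which encode basement membrane proteins, 1 was higher and 0 lower (median 0.65, -0.11 to 1.48, which held 0). That gene was LAMA4, at 210 CPM against 75.3. Broad families also lay above 0 in this comparison. The median was 0.38 (0.29 to 0.64) for small nucleolar and Cajal body RNAs. It was 0.20 (0.13 to 0.28) for histone and 0.16 (0.09 to 0.21) for ZNF zinc finger genes. The interval of the collagen median (0.12, -0.18 to 0.87) held 0. Whether a difference in RNA or library quality contributed was not tested. Members of the protocadherin cluster are near-identical in part, and whether their reads were told apart was not tested.

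Cholesterol synthesis genes had a median log2 ratio of -0.83 (upper bound -0.37) in the RA-treated library, and 13 of the 14 measured members lay below the median of all measured genes, -0.02. The list was picked because it was low, so this count describes the pattern and adds no separate test of it. Scaling between the 2 libraries multiplies every gene by 1 factor, so it cannot by itself set these members apart from the other genes. Fresh medium given on day 4 to the RA-treated aggregates only cannot be told apart from RA, since 0 libraries had the medium change without RA. An effect of RA itself stays open as well.

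NGFR was 3.13-fold higher in the RA-treated library. If crest cells alone expressed the specifiers, a larger share of these cells in the RA-treated aggregates would raise the other specifiers alike. That premise was not tested in the aggregates. In iPSCs some specifiers were expressed, such as CRABP1 at 274 CPM and ERBB3 at 87.7 CPM, while TFAP2B and NR2F1 had 0 counts. The median log2 ratio of the other crest specifiers was 0.53 (upper bound 0.62) over 21 genes, against a lower bound of 1.55 for NGFR. Of these 21 genes 7 were below 0, 3 were at least 2-fold higher and 1 was at least 2-fold lower. NGFR was taken up because it was high, so its place above that median adds no separate test. The other specifiers did not move alike. With the premise untested and NGFR picked for its ratio, these values cannot decide whether a larger crest share raised NGFR. Fresh medium given on day 4 to the RA-treated aggregates only cannot be told apart from RA, with 0 libraries to separate them, and regulation of NGFR by RA was not tested.

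Marker lists of neurons, surface ectoderm and amnion were lower in the sorted library than in the unsorted one. Noise that is independent between genes, and alike in genes of like expression, would put few lists at the extremes. However, 11 of 22 lists lay outside the middle 95% of their matched random lists. Of these, 9 lay below and 2 above (cholesterol synthesis and housekeeping). Ratios were shuffled 10000 times between genes of like expression, keeping the genes that lists share, and at most 6 lists then lay outside. The 3 lists of the pattern are among the 9 below. These shuffles do not cover noise shared between genes, which stays open. Independent noise that is larger in these markers than in other genes of like expression also stays open. The SD of the log2 ratios was 0.56, 1.01 and 1.11 in the neuron, surface ectoderm and amnion lists. It was 0.28 over all measured genes and 0.20 in the proliferation list. Removal of CD271-low cells of other types by the sort may account for the pattern. The highest of the 3 medians, of neuron genes, was -0.43 against a lower bound of -0.34 for the crest specifiers. The intervals of the neuron and crest specifier medians overlapped, however (-0.90 to -0.23 and -0.34 to 0.01). The surface ectoderm and amnion lists had too few measured members for an interval. Removal by the sort stays open because crest derivative, crest specifier, neural plate border and mesenchymal genes were among the 9 lists below. The most abundant members also differed little (TUBB3 152 against 149 CPM, and TFAP2C, of both other lists, 114 against 119, with a log2 interval of -0.18 to 0.05 that held 0). How specific the markers are was not tested, and other lists hold 1, 9 and 6 of the neuron, surface ectoderm and amnion genes. In the sorted library 11 of 16 neuron genes reached 5 CPM, against 12 in the unsorted one. For surface ectoderm the numbers were 3 of 18 against 5, and for amnion 1 of 16 against 4. A response to dissociation and sorting cannot be told apart from such removal either, with the immediate early and stress list at percentile 92.7 and 1 of its 12 members at least 2-fold higher.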
